A study of Drosophila melanogaster with 3 samples.

How the data were processed

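ChIP-seq peak lists of 3 biological replicates of embryos with an Antp-eGFP fusion, aged 0 to 24 h, were analysed. Per the labels, the fly line carries an eGFP exon inserted in an intron of Antp, the immunoprecipitation used an antibody against GFP, and chromatin was sonicated to 200 to 800 bp. A separate label of the samples names Antp as the antibody; the description of the pulldown was followed here. Replicates are numbered 1, 2 and 3 by their labels, and all belong to 1 group, so no test between groups was made and p-values never measure a difference between groups of animals.

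The deposited files are narrowPeak lists in the assemblies dm6 and dm3. Per the file descriptions deposited with the samples, each replicate's list of 30000 entries was called from its own alignments against a control, a further list of 30000 was called on the pooled alignments, and the optimal IDR list was derived from these. The signal deposited by the authors for each peak is the peak caller's own strength value, and it was used only to rank and describe peaks within a list. The deposited −log10 q-value of each peak was used only as an alternative ranking, in which 3253 of the 4351 IDR peaks are tied at the highest value. The aligner, the peak caller and the IDR threshold are not given in the sources used here. On the dm6 lists it was checked that the IDR list equals the 4351 pooled entries with the highest signal. In the IDR list 3040 of 4351 peaks have a width of exactly 390 bp, so overlap shares depend partly on the caller's fixed width, and 7 peaks repeat an interval with another summit. Because the files hold no read counts, the depth per replicate is unknown. Binomial intervals are exact (Clopper-Pearson, 95%), are over peaks, and cover counting error only.

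Positions were placed on the dm6 genome sequence and Ensembl release 115 gene models of the same assembly. Coordinates are 1-based. No reference of dm3 was used here, so dm3 lists served only for counts, widths, signals and shares per arm. Peaks were matched to replicate entries by a reciprocal overlap of 50%; ranks of named peaks came from the nearest replicate summit within 100 bp. Each summit was placed in 1 class, in the order promoter (within 500 bp of a TSS), 5' UTR, CDS, 3' UTR, other exon, intron, intergenic, and compared with 1000 draws of random positions on the same chromosomes outside sequence gaps. Arm shares were tested with exact binomial tests. The random positions take no account of mappability.

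A gene was called bound when an IDR summit lay in its span or within 1 kb. Each of 31 gene lists was compared with the other protein-coding genes (all genes for tRNA and snRNA lists) in 20 strata of span length by an exact stratified hypergeometric test, two-sided, with Benjamini-Hochberg adjustment over lists and Mantel-Haenszel odds ratios. Lists overlap in some members. Of the listed symbols 3 were updated to current ones (hry, nanos and Delta). Genes named in the text follow a rule: all Hox genes with tsh, exd and hth; from each other list up to 4 bound members with the highest peak signal and up to 2 unbound members with the longest span; the genes at or nearest the 10 strongest peaks; and the 5 genes with the most summits. From the longer lists the text gives the first of these. Neighbouring genes that describe where a named peak lies (such as modSP, CG46458 and gro) were added after the values were seen.

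Motifs were 11 fixed sequences, searched on both strands in windows of 201 bp centred on summits. Control windows lay 1 kb to either side and did not touch an IDR peak, and Fisher's exact test was used with adjustment over motifs. Matched windows were random windows of the same promoter class and the same 2% bin of GC content. Trends with peak strength used permutation tests with 100000 resamples. Alternatives were another overlap rule, the 2175 strongest peaks alone, each replicate's own 4351 strongest entries with each replicate left out in turn, TSS distances of 250 and 1000 bp, peak midpoints, gene spans with no extension or 5 kb, the nearest TSS only, 5 strata or none, motif windows of 50 and 250 bp, controls at 2 kb, matched windows, 10 bins, ranking by q-value and the dm3 lists. The groups, tests, gene lists, motifs and these alternatives were chosen before the data were examined, except that for the agreement of ranks the other overlap rules and leaving out replicates were added later.

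The procedures were tested on simulated data. A planted gene list with 95% of its genes bound was called in 18 of 20 simulated sets over 13968 genes. Smaller differences were not simulated. Of 540 tests of unplanted lists, 2.78% had an unadjusted p under 0.05. A DRE planted in 30.5% of 4351 windows was recovered in 31.0%, with 0 of 10 unplanted motifs called. The planted share is far above the 4.80% of real summits with a DRE. The simulated windows lay at random positions, so their flanks did not differ in composition as those of the real summits do. The 0 of 10 therefore does not measure false calls that come from composition. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.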

Results

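Antennapedia (Antp) is a homeodomain transcription factor that gives thoracic segments their identity in the fly. The series maps where a fusion of this protein with enhanced green fluorescent protein (eGFP) sits on chromatin in whole Drosophila melanogaster embryos aged 0 to 24 h, with males and females mixed. Chromatin was sheared by sonication to fragments of 200 to 800 bp, and the fusion was pulled down with an antibody against GFP (ChIP-seq). There is 1 group of 3 biological replicates, so no groups are compared, and the measurements are the positions, strengths and sequences of the peaks. Each replicate has a list of 30000 ranked entries that mixes peaks with background, the pooled reads have another list of 30000, and the deposited IDR list (irreproducible discovery rate, a filter on agreement of ranks between replicates) holds 4351 peaks in dm6. Read totals are not part of these lists, so the depth behind each peak is unknown. Control and untagged immunoprecipitations were not analysed here.

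Antp-eGFP gave 4351 IDR peaks that covered 1.06% of the genome sequence. They were the 4351 strongest entries of the pooled list, with peak signals (the authors' values) from 103 to 4656, a 45.0-fold range. The 435 strongest peaks held 32.0% of the summed signal. The strongest peak was at the promoter of Ugalt in all 3 replicates. Of the IDR peaks, 86.6% ± 0.670 (SD, n = 3) shared at least 50% of their length, in both directions, with an entry of a replicate's list, and 73.2% ± 1.90 (SD, n = 3) did so with 1 of that replicate's 4351 strongest entries. In all 3 replicates at once, 2269 peaks met the stricter condition. A required overlap of 1 bp raised that number to 3027 and the mean shares to 99.8% and 86.8%, so much of the shortfall lay in peak borders. Peak signals of replicate pairs had a mean Spearman rho of 0.697 ± 0.00990 (SD over 3 pairs) across matched peaks, which are not independent replicates. No pair of replicate lists shared more than 1 interval with identical borders, and none had the same signal. The IDR list was derived from these same replicates by their agreement. The shares and correlations at its peaks are therefore not an independent measure of reproducibility.

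Among the 10 strongest peaks, 6 had their summit within 500 bp of an annotated transcription start site (TSS). Peak 1 lay at X:2703675 to 2704115 with its summit 34 bp from the TSS of Ugalt, a UDP-galactose transporter, and had a signal of 4656. Peak 2, with a signal of 4191, lay at 2L:480850 to 481332 in an intron of ush, a cofactor of GATA factors, 1393 bp from the TSS of the nested gene cbt. Peak 3, with a signal of 3921, lay at 3L:19590411 to 19590811 at the promoter of CG14100, 97 bp from its TSS. It also lies just beyond the 3' end of ash1, which encodes a histone methyltransferase of the trithorax group. The same peaks took ranks 1, 2 and 3 in every replicate. Peak 4 was in px (2R:22514095 to 22514520), peak 5 was intergenic, 903 bp from the TSS of lncRNA:CR45643, and peak 6 was in an intron of Lk6, a protein kinase. Peaks 7 and 8 were at the promoters of CG1888 and of Chro, a chromosomal protein. Peak 9 lay 11922 bp from the nearest TSS, that of CG13323, and peak 10 was at the promoter of ph-p, a Polycomb group gene, with a rank of 10.3 ± 2.52 (SD, n = 3). The genes with the most summits in their span were CG1677 with 14, ush, kirre and sbb with 13 each, and Raf with 12. All 5 have spans of 48405 bp or more, and long spans catch more summits by chance.

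Promoters held most of the Antp-eGFP summits. Within 500 bp of a TSS lay 54.9% of IDR summits (95% exact binomial interval 53.4 to 56.4), against 13.6% ± 0.512 (SD over 1000 draws) of random positions on the same chromosomes. Coding sequence held 0.667% of summits against 13.7% of random positions, and 3' UTRs held 0.781% against 4.47%. Introns held 30.8% against 39.6%, and intergenic sequence 11.6% against 27.0%. Annotated transposable elements held 8 summits, 0.184%, against 5.76% of random positions. Each of these differences had a two-sided permutation p of 0.002, the smallest that 1000 draws can give. The median summit lay 346 bp from a TSS, 29.7% lay within 100 bp of one, and 13.0% lay over 5 kb away. In the 4351 strongest entries of each replicate the promoter share was 54.2% ± 0.127 (SD, n = 3). The coding share was less uniform: replicate 1 had 143 summits in coding sequence where replicates 2 and 3 had 42 and 51, and the mean GC content of its summit windows was 41.0% against 38.8% and 39.8%.

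**Figure D1:**
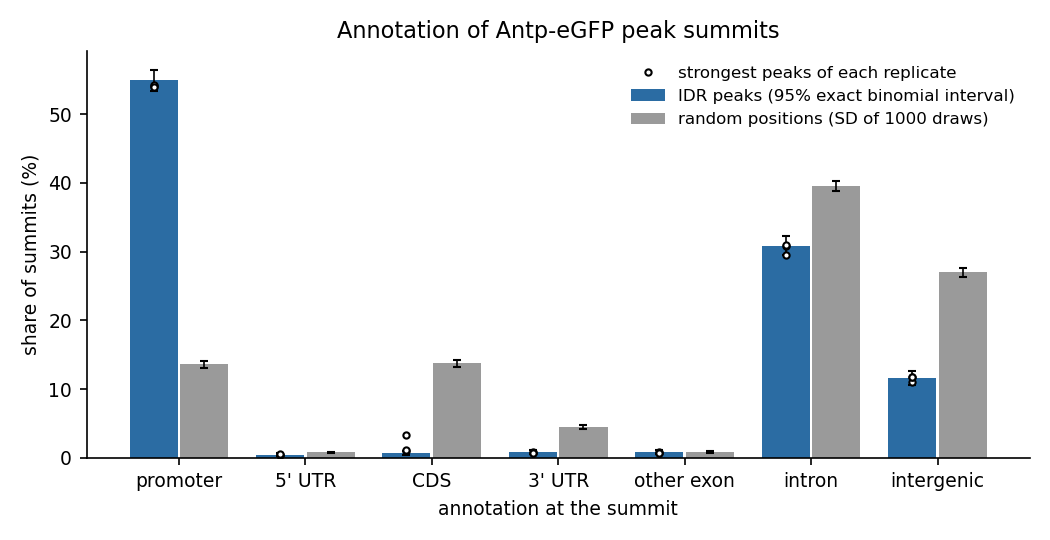
Share of summits in each annotation class (y axis, percent) for the 4351 IDR peaks (blue, 95% exact binomial interval), for random positions on the same chromosomes (grey, SD over 1000 draws) and for the 4351 strongest entries of each replicate (open circles). Promoters hold 54.9% of IDR summits and 13.6% of random positions, and the circle at 3.29% in coding sequence is replicate 1.

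The X chromosome carried 37.4 peaks per Mb, and the dot-like chromosome 4 carried 6.01. Of all peaks, 20.2% were on X, which holds 17.1% of the sequence (exact binomial test, adjusted p = 4.79e-07 over 7 arms). Arm 2L had 34.4 peaks per Mb (exact adjusted p = 0.0221), and 2R, 3L and 3R had 30.0 to 32.1 with adjusted p-values of 0.0954 or more. Chromosome 4 had 8 peaks, below its share of the sequence (exact adjusted p = 7.39e-10). Chromosome Y had 0 peaks, and a count of 0 allows at most 0.880 per Mb. Y and 4 are rich in repeats, where reads map poorly, and neighbouring peaks are not independent, so these p-values are too small. The sequence total includes Y and 4, which lowers the share expected for every other arm. The calls for X and 2L, and the lack of a call for 3L, were not tested without them. That for 2L, with 18.6% of peaks against 17.2% of the sequence, is therefore uncertain. Summits clustered along the arms: the median gap between neighbours was 10718 bp against 21079 ± 340 bp (SD over 1000 draws) at random, and 16.8% of gaps were under 2 kb against 6.37% (permutation p = 0.002 for both, the smallest possible).

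Antp itself held 6 IDR summits, the most of any Hox gene, and 6 of the 8 Hox genes had at least 1. With 102976 bp Antp also has the longest span of the 8, and the number of summits was not tested against length. The Hox genes give body segments their identity. Antp (FBgn0260642, 3R:6896253 to 6999228, minus strand) had its strongest summit in an intron at 6914579, with a signal of 319 and a rank of 895 ± 306 (SD, n = 3) in the replicate lists. Of its other summits, 4 were intronic and 1, at 6933060, lay 220 bp from an annotated Antp TSS. Abd-B had 3 intronic summits with signals of 105 to 112. Ubx had 1 intronic summit at 16704446 with a signal of 136, and 1 at 16655848 beyond its 3' end, 186 bp from the TSS of the neighbour modSP. Scr had 1 summit 113 bp from its TSS, with a signal of 138, while abd-A and pb had 1 intronic summit each, with signals of 105 and 116. The genes lab and Dfd had none. Genes of the same span lengths would give 4.30 bound Hox genes, so 6 of 8 did not differ detectably from length alone (odds ratio 2.73, exact stratified test, adjusted p = 0.544). No Hox summit ranked among the 800 strongest peaks, and 5 of the 6 Antp summits also lie in the overlapping coding gene model CG46458.

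**Figure D2:**
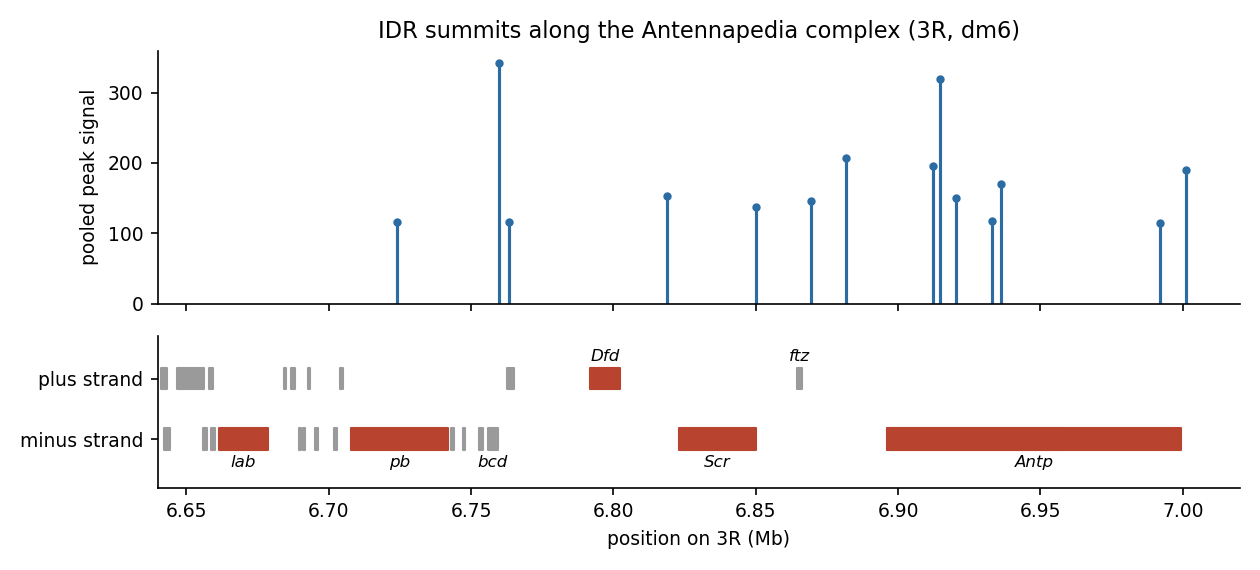
IDR summits along the Antennapedia complex on 3R in dm6. The upper panel gives the pooled peak signal (y axis, the authors' units) against position (x axis, Mb), and the lower panel gives protein-coding gene spans by strand, with Hox genes in red; the highest of the 6 summits in Antp reaches 319, and lab and Dfd have none.

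Ribosomal protein genes and small nuclear RNA genes were bound more often than genes of the same span length, and chemosensory receptor and cuticle protein genes less often. A gene counts as bound here when an IDR summit lies in its span or within 1 kb of it, which held for 4186 of 13968 protein-coding genes (30.0%). Of 92 ribosomal protein genes 59 were bound, where span length alone gives 19.8 (odds ratio 7.11, exact stratified test, adjusted p = 1.82e-17 over 31 lists). RpL32, RpL23A, RpS27 and RpL34b had the strongest peaks of the list, with signals of 937, 863, 846 and 804 and summits 17 to 142 bp from a TSS, which for RpL32 is that of the neighbour CG7943. RpL5 and RpL3 were the longest members without a peak. Of 32 snRNA genes, whose products take part in splicing or, as 7SK, in transcription control, 11 were bound against 3.09 (odds ratio 5.35, exact adjusted p = 0.00145). Among them were snRNA:7SKa, snRNA:U2:34ABb, snRNA:U5:35D and snRNA:U1:95Ca, with signals of 516, 279, 234 and 230, though the summits counted for snRNA:7SKa and snRNA:U5:35D are nearest the TSSs of CG1142 and ND-B17. Copies of snRNA and ribosomal protein genes can share reads, so single members are uncertain. The snRNA call ended with spans extended by 5 kb (exact adjusted p = 0.430), without the length strata (0.527) and with the 2175 strongest peaks alone (0.246). Genes of the same span length were for this list taken from all genes, coding or not. Their expected share was 9.65%, while 25.9% of all genes were bound when length is ignored.

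Of 179 genes for odorant, gustatory and ionotropic receptors, which serve smell and taste, 7 were bound against 47.8 by length (odds ratio 0.109, exact stratified test, adjusted p = 6.42e-15). The strongest were Ir68b, Or88a, Gr89a and Ir60e, with signals of 374, 295, 269 and 224. All 4 of these summits lay outside the gene span, and those of Ir68b, Or88a and Ir60e were at the promoters of the neighbours yps, CG12402 and CG13585. Of 115 cuticle protein genes 2 were bound against 23.1 (odds ratio 0.0574, exact adjusted p = 2.20e-08), Cpr76Ba with a signal of 565 and Cpr73D with 104. That call ended when only summits inside the span counted (1 gene bound against 5.19, odds ratio 0.121, exact p = 0.0497, adjusted p = 0.257). A summit near several genes counts for each, so genes that sit together, as many receptor and cuticle genes do, are not independent.

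At an unadjusted p under 0.05 another 5 lists lay above their length-matched share and 1 below, none of which passed the adjustment over 31 lists. Of 20 Polycomb and trithorax group genes, which keep Hox genes off or on, 14 were bound against 8.59 (exact adjusted p = 0.0835). The strongest peaks counted were those of ash1, ph-p, osa and Trl, with signals of 3921, 2408, 1402 and 1077, that of ash1 being the peak at the CG14100 promoter, and Pc and pho had none. Of 11 ecdysone response genes 10 were bound against 5.95 (exact adjusted p = 0.0835), led by Hr4 with 9 summits, Hr3, EcR and Eip75B. Of 13 cell cycle genes 10 were bound against 5.05, with CycB and fzr at signals of 1665 and 1166 (the latter nearest the TSS of CG3009), and of 10 glycolysis genes 8 against 3.56, with Gapdh2 and Pgk at 423 and 397 (exact adjusted p = 0.0559 for both lists). Of the 11 E(spl) complex genes, targets of Notch signalling, 5 were bound against 1.80 (exact adjusted p = 0.135), the strongest being E(spl)m8-HLH with a signal of 275, at a summit nearest the TSS of gro. Of 13 neuron genes 2 were bound, elav and ChAT, against 6.75 (exact adjusted p = 0.0657), and the sodium channel gene para and the calcium channel gene cac had no peak. The Polycomb and trithorax list did pass with the 2175 strongest peaks (exact adjusted p = 0.0206) and for genes bound in the strongest entries of all 3 replicates (0.0134), and without replicate 1, 2 or 3 (0.0345, 0.0291 and 0.0294). Its adjusted p ranged from 0.00132 to 0.543 over the settings. The E(spl) list passed with the nearest TSS only (5 bound against 1.06, exact adjusted p = 0.0272, range 0.0272 to 0.822). Ecdysone and glycolysis genes passed with 5 strata (exact adjusted p = 0.0476 for both, ranges 0.000288 to 0.922 and 0.00609 to 0.630), and ecdysone genes also without replicate 1 (0.0471). Without length strata the Polycomb and trithorax, ecdysone, glycolysis and cell cycle lists passed, the last with an exact adjusted p of 0.00284 in a range up to 0.872.

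Lists of patterning genes had no call in either direction. Of the 9 pair-rule genes, which set alternate segments, 0 were bound against 2.92 (exact stratified test, adjusted p = 0.150), opa and run included. Of 14 gap genes 2 were bound, bcd with a signal of 342 and cad with 167, against 4.94 (exact adjusted p = 0.336). Among 14 segment polarity genes 4 were bound against 6.23: nkd, ptc, dsh and smo, with signals of 224, 222, 146 and 136, that of smo at the promoter of CG17078. Of 20 antenna, eye and leg genes 6 were bound against 9.81, among them ct at 425 and Lim1 at 311. Of the 6 Hox cofactors and homeotic modulators, hth held 6 summits up to a signal of 204 and tio held 1, while tsh and exd had none. The adjusted p-values of the last 3 lists in the exact test were 0.306 or more. With only the gene of the nearest TSS counted, 4 of 9 pair-rule genes (against 1.87), 5 of 14 gap genes (3.34), 3 of 14 segment polarity genes (4.53), 6 of 20 antenna, eye and leg genes (7.45) and 3 of 6 Hox cofactors (2.10) were bound, again with no call.

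Lists of tissue, signalling and housekeeping genes other than those above had no call, and most hold 8 to 20 genes, too few to exclude sizeable differences. Bound were 5 of 18 neural fate genes (7.16 by length) with brat at 568, 5 of 16 mesoderm genes (7.05) with Mef2 at 484, 5 of 8 glia genes (3.28) with moody at 1451, and 10 of 20 signalling genes (9.13) with spi at 700. Muscle structure had 3 of 13 (5.48) with sls at 366, trachea 4 of 9 (3.93) with rib at 390, gut 4 of 8 (3.67) with fkh at 404, and epidermis 2 of 8 (3.67) with grh at 276. Hemocytes had 2 of 9 against 4 by length, ush at 4191 and Hml at 119. The germline had 3 of 9 (3.29) with nanos at 350, testis 2 of 15 (3.79) with topi at 463, and chorion and yolk 0 of 9 (1.81). Heat shock genes had 5 of 9 (2.36) with Hsp27 at 541 and Hsp83 at 435, and the proteasome 14 of 48 (11.1) with Rpn5 at 1211. The summits counted for nanos, topi and Rpn5 are nearest the TSSs of their neighbours CG11779, RpS29 and Hpf1. Of 295 tRNA genes 28 were bound against 29.7, and 17 against 13.2 by the nearest TSS. The exact adjusted p-values of these 15 lists ranged from 0.280 to 1.

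**Figure D3:**
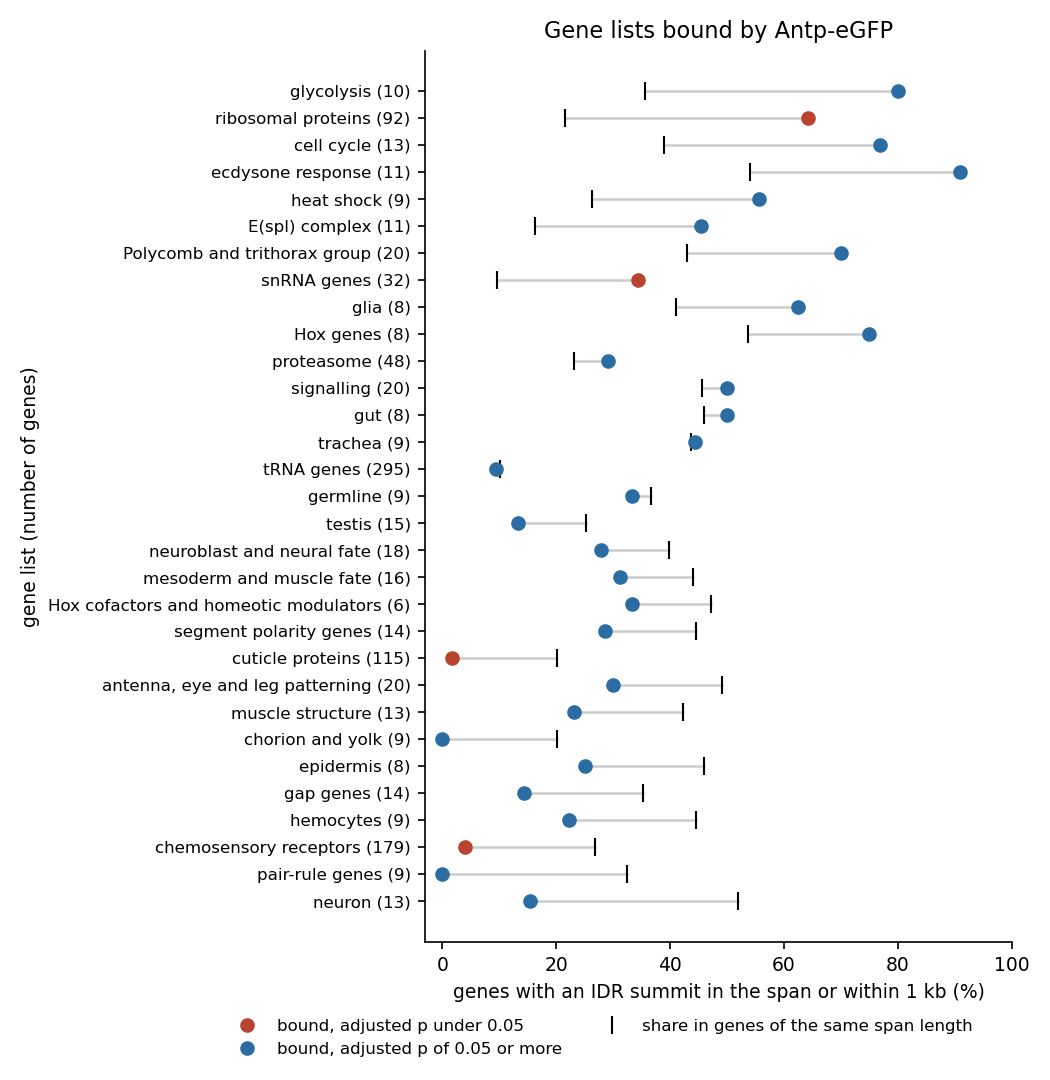
Percent of genes bound (x axis) in each of 31 gene lists (y axis, number of genes in brackets), with the share of genes of the same span length as a black tick. Red points had an adjusted p under 0.05: ribosomal proteins at 64.1% and snRNA genes at 34.4% lie above their ticks, cuticle proteins at 1.74% and chemosensory receptors at 3.91% below.

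Sites of housekeeping promoters, and not the Hox core, were over-represented at the summits. The DRE (TATCGATA, bound by DREF) occurred within 100 bp of 4.80% of IDR summits and in 0.477% of control windows 1 kb to either side (odds ratio 10.5, Fisher's exact test, adjusted p = 2.55e-58 over 11 motifs). Against random windows matched on GC content and on promoter class the odds ratio was 3.61 (exact adjusted p = 5.12e-20). The class is a position within 500 bp of a TSS, so neither the distance to the TSS inside it nor promoter activity was matched. Ohler1 (GGTCACAC, the core promoter motif of M1BP) occurred at 2.80% against 0.563% (odds ratio 5.10, exact adjusted p = 5.53e-23), and its matched odds ratio was 2.76. Read backwards as a composition control, Ohler1 was also more frequent at summits than in matched windows (odds ratio 3.32), while the backward DRE was not (1.41, exact adjusted p = 0.497). In the strongest entries of the replicates the DRE occurred at 4.80% ± 0.193 and Ohler1 at 2.87% ± 0.119 (SD, n = 3).

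The Hox core TAATKR occurred at 40.3% of IDR summits and in 38.9% of flanking windows (odds ratio 1.06, Fisher's exact test, adjusted p = 0.203). Against flanks it passed in windows of 250 bp (70.8% against 68.1%, exact adjusted p = 0.00323) and in the strongest entries of replicate 2 (41.4% against 38.4%, exact adjusted p = 0.00324), not in those of replicates 1 and 3. Against matched windows, at 44.5%, it was less frequent (odds ratio 0.843, exact adjusted p = 0.000259), so its direction depends on the control. Flanking windows have a GC content of 43.3% against 39.2% at summits, a difference the matched windows remove. The composite site of Hox proteins with Exd, TGATTWAT, occurred at 2.87% against 3.05% in flanks (exact adjusted p = 0.682) and 3.98% in matched windows (odds ratio 0.714, adjusted p = 0.0121). Hth and GATA sites were more frequent than in flanks (odds ratios 1.27 and 1.16, exact adjusted p = 0.00453 and 0.00214), and the Twist E-box was less frequent (0.876, adjusted p = 0.00850). Read backwards, the Hox core was further above flanks than forward (1.19, exact adjusted p = 3.08e-05), as were Hth and GATA (1.37 and 1.54). The backward DRE passed there too (2.38, exact adjusted p = 0.00815), so flanks differ in composition. Matched windows differ too, since there the backward GATA (1.17, exact adjusted p = 0.00461) and Twist E-box (1.25, exact adjusted p = 0.00168) passed. The forward Hth, GATA and Twist E-box did not hold against matched windows, where the odds ratios were 1.08, 1.02 and 1.03 and the smallest exact adjusted p was 0.657. GAGA did not pass against flanks (odds ratio 1.18, exact adjusted p = 0.133) and passed against matched windows (1.84, adjusted p = 1.39e-06). Zelda, Pho and the CA repeat passed in neither, with adjusted p-values of 0.479 or more.

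**Figure D4:**
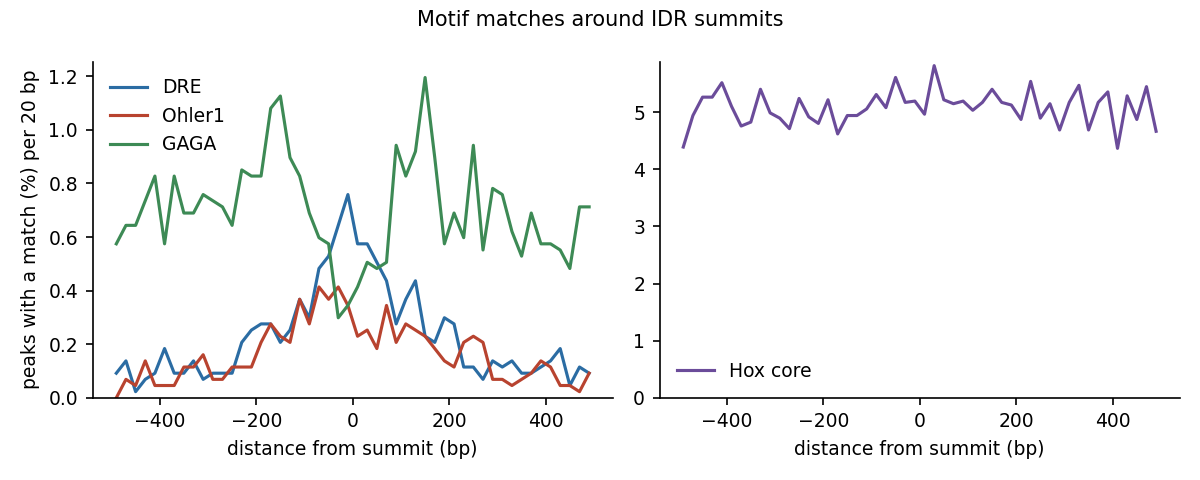
Percent of the 4351 IDR peaks with a motif match in each 20 bp bin (y axis) against distance from the summit (x axis, bp), for DRE, Ohler1 and GAGA on the left and the Hox core on the right. The DRE line peaks at 0.758% next to the summit. GAGA is at 0.345% in the same bin, lowest at 0.299% in the next bin to the left, and higher farther out on both sides. The Hox core line is close to 5% throughout.

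Stronger Antp-eGFP peaks were more often at promoters. The promoter share was 61.0% in the 871 strongest peaks and 48.4% in the 870 weakest (Spearman rho 0.0789 across 4351 peaks, permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 0.000120 over 12 features). Ohler1 fell with strength, from 3.68% of the weakest to 1.49% of the strongest peaks (rho -0.0466, permutation test, adjusted p = 0.0119). The Hox core was present in 40.0% of the strongest and 39.0% of the weakest peaks (rho -0.00344, adjusted p = 0.835). The DRE was at 3.21% in the strongest, 6.21% in the middle and 2.99% in the weakest of the 5 bins, with no monotone trend (rho 0.00673, adjusted p = 0.835). Peaks are not independent replicates, and these trends describe the pooled list.

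**Figure D5:**
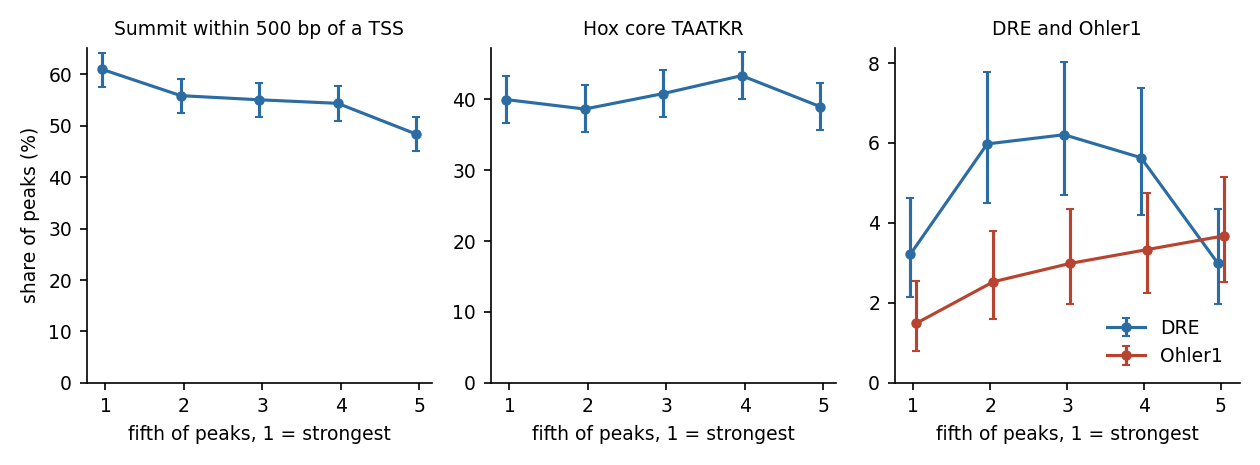
Percent of peaks (y axis) with a summit within 500 bp of a TSS (left), a Hox core site (middle), and a DRE or Ohler1 site (right) in 5 bins of IDR peaks by signal (x axis, 1 = strongest), with 95% exact binomial intervals. The promoter share goes from 61.0% to 48.4%, and Ohler1 from 1.49% to 3.68%.

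The dm3 version of the IDR list held 4181 peaks, 170 fewer than in dm6. Both lists had a median peak width of 390 bp and a top signal of 4655 to 4656, and their lowest signals were 106 in dm3 and 103 in dm6. The X chromosome held 20.2% of peaks in both assemblies and chromosome 4 held 8 peaks in both. Of the dm3 IDR peaks 1 lay outside the main arms, against 0 in dm6. No positions were carried from dm3 to dm6.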

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

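Of the tests in this part, the test on tRNA genes was chosen only after its result had been seen. The patterning lists were pooled, and their nearest TSS and 5 kb settings added, after results had been seen. The interval for tRNA genes by the nearest TSS was also added then. The 20 kb setting was chosen after the patterning lists had been seen below their share, but its bound was set before its own result was known. Of the pooled entries below the IDR list, 25181 did not touch an IDR peak. Among these, 3602 had a summit within 100 bp in the lists of all 3 replicates, against a mean of 240 for random positions over 20 draws. This signal lies in entries that the comparisons above do not use, and the pooled list was made from the same reads, so the lists are not independent. In dm3, 50 pooled entries lie on heterochromatin or unplaced sequence outside the main arms, which the dm6 lists do not have, and their positions were not analysed here.

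Within 100 bp of IDR summits the Hox core was not in excess over flanking or matched windows, although against flanks, which are richer in GC, it passed in windows of 250 bp (odds ratio 1.14, exact adjusted p = 0.00323) and in replicate 2 (1.13, exact adjusted p = 0.00324). Promoter peaks may have diluted an excess at distal peaks, but summits over 1 kb from a TSS also had the core less often than matched windows (odds ratio 0.809, 95% interval 0.700 to 0.935). Weak peaks could have diluted it too, yet in the 870 strongest peaks the odds ratio was 0.766 (0.630 to 0.930). Entries below the IDR list, where bound sites might have been lost, gave 1.01 (0.975 to 1.05). The results at distal and at the strongest peaks argue against dilution as the cause, but only for the comparison with matched windows. Distal peaks were not set against flanks, and peaks both strong and distal were not tested. Against flanks the 2175 strongest peaks gave an odds ratio of 1.07 (Fisher's exact test, adjusted p = 0.314). The result of the entries below the list cannot decide on the threshold, because these entries mix peaks with background. Only 3602 of the 25181 were found in all 3 replicates, and they were not tested apart. The threshold, indirect binding, sites outside the fixed patterns and signal unrelated to the fusion remain open. No biological explanation was tested because there is no second group.

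With summits in the span or within 1 kb, 13 of the 60 genes of 5 patterning lists counted as bound against 25.7 by span length (odds ratio 0.340); these lists were pooled because each had been seen below its share, and the Hox list, above its share, was not among them, so no p-value is given and no deficit is established. With spans extended by 5 kb the odds ratio was 0.315, and with only the gene of the nearest TSS counted it was 1.04 (19 of 60 against 18.6). For peaks beyond the span as the cause, the bound set beforehand, an odds ratio of 1 or less with 20 kb, was met at 0.504, but that bound was badly chosen: a window of fixed size also catches the peaks of neighbours, and the nearest TSS, which counts each summit for 1 gene at any distance, gave 1.04, so the explanation stays open. Whether the IDR threshold removed peaks at these genes is also open. Entries below the list touched 54 of the 60 genes against 50.5 (odds ratio 1.71), a measure near saturation. The mean number of such entries was 4.58 per gene against 3.98 in length-matched genes, a difference that was not tested. No biological explanation was tested.

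Peaks gathered at ribosomal protein genes. In gene-dense regions a neighbour's promoter may lend a gene its peak, but with only the gene of the nearest TSS counted the odds ratio was 6.80 (exact stratified test, adjusted p = 1.28e-14). Signal could also gather at any highly transcribed gene whatever protein is pulled down; tRNA genes, which are heavily transcribed, do not decide this, with an odds ratio of 0.917 (95% interval from resampling the listed genes 0.574 to 1.26) within 1 kb of the span and 1.44 (0.771 to 2.36) by the nearest TSS. That explanation stays open, since neither expression values nor a control pulldown were analysed here. No biological explanation was tested.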

How the results depend on the processing

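The IDR peak support share, the top-N support share and the replicate rank agreement moved with the overlap rule or the peaks used. With 1 bp of overlap 99.8% of IDR peaks were in a replicate's list and 86.8% in its strongest entries; with summits within 100 bp the shares were 97.2% and 83.9%. The 2175 strongest peaks gave 75.3% for the first share and a rank agreement of 0.823. Rank agreement was 0.793 with 1 bp of overlap and 0.782 with summits, and ranged from 0.687 to 0.706 with each replicate left out; these alternatives were chosen after the data were seen.

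Among gene lists, Hox genes (75.0% bound) had an adjusted p of 0.0386 in Fisher's exact test without length strata. With the 2175 strongest peaks alone, only Antp of the Hox genes stayed bound, by its summits of rank 860 and 1820. Cuticle proteins lost their call with no extension (0.870% bound). The snRNA genes lost theirs with 5 kb (43.8%), without strata (34.4%) and with the 2175 strongest peaks (15.6%). The number of lists above was 1 with 5 kb, 4 with 5 strata, 4 without replicate 1 and 6 without strata, and lists below numbered 1 with no extension and 3 without strata. The added list is of tRNA genes (28 bound against 76.5, odds ratio 0.295, exact adjusted p = 1.44e-11, range over settings up to 1), whose short spans that test ignores.

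Motif results depended on window and control. The Hox core odds ratio was 1.14 in windows of 250 bp, a call above the flanks (exact adjusted p = 0.00323), and 0.843 against matched windows, 0.797 at promoters and 0.816 at other summits, a split chosen after the data were seen. Hox-Exd had 0.714 against matched windows. The Hth odds ratio was 1.16 with controls at 2 kb, 1.08 matched, 1.08 at promoters, 0.853 at other summits and 1.21 as the replicate mean, or 1.23, 1.19 and 1.202 without replicate 1, 2 or 3. GAGA had 1.77 in windows of 250 bp, 1.46 at 2 kb, 1.84 matched, 1.58 at promoters and 2.19 elsewhere. GATA had 1.13 in windows of 50 bp, 1.02 matched, 0.901 at promoters, 1.10 elsewhere and 1.14 as the replicate mean, or 1.17, 1.12 and 1.12 without replicate 1, 2 or 3. The Twist E-box had 0.894 in windows of 50 bp, 1.03 matched, 0.918 in the 2175 strongest peaks, 0.936 at promoters, 1.05 elsewhere and 0.916 as the replicate mean, or 0.905, 0.917 and 0.926 without replicate 1, 2 or 3. The CA repeat had 0.629 at 50 bp and 1.30 at 250 bp. Away from promoters the DRE had 0.665 (8 windows against 12) and Ohler1 3.35 (10 against 3). Neither was a call (Fisher's exact test, adjusted p = 0.553 and 0.229). Pho had 0.688 there, a call below matched windows (exact adjusted p = 0.00613). Of the 4351 peaks 3253 are tied at the highest q-value, so ranking by q-value mostly sets the weakest peaks apart and says little about trends with strength. In that ranking the trend of motif by peak rank: DRE was a rho of 0.0504 (permutation test, adjusted p = 0.00534), and that of motif by peak rank: Ohler1 was -0.0122.

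With the 2175 strongest peaks, the shares of annotation classes and arms and the clustering had the same calls. The promoter share also had the same call with TSS distances of 250 and 1000 bp and with peak midpoints. The dm3 arm shares and the replicate means of the promoter share were not tested. Ranking by the score column was not run, because all peaks carry the same score.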

Other observations

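The tests in this part were all chosen after the main results had been seen, but the 7-mer test on chromosomes 3 and X was set before its result was known. Gene families taken by symbol add to the picture of the fixed lists: of 31 families, 3 were bound more often than genes of the same span length and 7 less often, by the exact stratified test adjusted over the families. Mitochondrial ribosomal protein genes were bound in 30 of 73 cases against 13.0 (odds ratio 3.28, exact adjusted p = 4.60e-05). Rab GTPase genes, which act in vesicle traffic, were bound in 17 of 31 cases against 9.80 (exact adjusted p = 0.0296), and snoRNA genes in 43 of 257 against 25.1 (adjusted p = 0.000848), the latter often inside host genes. Other parts of the basic machinery did not pass, such as translation initiation factors with 20 of 44 against 13.4 (exact adjusted p = 0.0928) and oxidative phosphorylation subunits with 9 of 40 against 7.98 (adjusted p = 0.862).

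The 7 families below their share were the following. The dpr and DIP cell surface proteins had 3 of 32 bound against 16.5 (odds ratio 0.107, exact adjusted p = 2.23e-05). Cytochromes P450 had 7 of 85 against 24.5 (exact adjusted p = 4.60e-05), Osiris proteins 1 of 25 against 6.92 (exact adjusted p = 0.0193) and mucins 0 of 13 against 4.77 (exact adjusted p = 0.0169). Histone genes had 3 of 118 against 14.2 and rRNA genes 0 of 101 against 10, but both are tandem repeats that share reads. For lncRNA genes the count was 250 of 1945 against 311 (odds ratio 0.716, exact adjusted p = 8.33e-05).

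A hypothesis was that a sequence outside the 11 fixed motifs marks the summits. On chromosome 2, 117 of 7918 7-mers were over-represented against matched windows, and the leading 5 outside the fixed motifs were CACAGTG, ACAGTGG, CACTGTA, CACACTG and CACTGAG, which all contain CACTG or its reverse complement. All 5 were over-represented on chromosomes 3 and X, which had not been used to find them, with odds ratios of 2.02 to 6.19 (Fisher's exact test, largest adjusted p = 7.58e-08). There CACTG was within 100 bp of 53.7% of summits against 29.1% of matched windows (odds ratio 2.83, 95% interval 2.53 to 3.17). The odds ratio was 4.06 (3.42 to 4.83) at summits over 500 bp from a TSS and 2.10 (1.80 to 2.45) at promoters. The DRE, in contrast, was in excess at promoters (odds ratio 4.48), in summits of all chromosomes and against another draw of matched windows. Elsewhere it was in only 8 windows against 12 (0.665, exact adjusted p = 0.553). CACTG was not centred on the summit. In bins of 20 bp over all IDR peaks it was at 6.71% and 6.83% directly left and right of the summit. It was highest, at 8.46% and 8.80%, in the bins centred 70 bp to the left and right. The Ohler1 motif read backwards contains CACACTG, so this composition control may be raised by the same sequence. CACACTG also begins with CACAC, the last 5 bases of the forward Ohler1 pattern GGTCACAC. Some of its matches may therefore be Ohler1 sites that run on into CACTG, so this 7-mer is not clearly separate from the fixed motifs. That overlap was not tested. Which protein reads CACTG, if any, was not tested either.

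Among the pooled entries below the IDR list the DRE was also over-represented against matched windows (1.09% against 0.425%, odds ratio 2.59, Fisher's exact test, p = 2.76e-18). In replicate 1 the 143 coding summits had a mean GC content of 59.4%, and the 42 and 51 of replicates 2 and 3 had 57.7% and 58.4%.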
